A study of Homo sapiens with 2 samples.

How the data were processed

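Gene expression was measured in U251 cells, a human glioma cell line, on the Affymetrix HG-U133_Plus_2 array, which reads each transcript with one or more sets of short probes near its 3' end. The series holds 2 arrays, 1 of cells transfected with a control and 1 of cells transfected with miR-31, a microRNA. Total RNA was extracted with trizol and biotin-labelled with a 3' IVT kit, per the labels' protocols. The labels do not say what kind of construct was transfected or how long before harvest.

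The authors deposited 1 table of linear intensity values, 1 per probe set and array, for 54675 probe sets. The software that made the values is not given in the sources used here. The mean intensity after leaving out the lowest and highest 2 percent of probe sets was 500.1 on both arrays, so each array had been scaled to a common level. Deposited intensities ran from 0.124 to 44755 on the control array and from 0.109 to 48627 on the miR-31 array, and their medians were 63.2 and 67.6. No detection calls were used here, so a low value cannot be separated from background. Each group has 1 array, and this number limits the precision: no replicate spread exists, and no p-value was computed.

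Values were taken as log2(intensity + 16), and the ratio of a gene is the miR-31 array minus the control array on that scale, which understates the change of dim genes. Of the probe sets, 41097 carried 1 gene symbol in the platform annotation supplied with the data, 1801 carried several and 11777 are unnamed here. Only those with 1 symbol were used for genes, and 41043 of them matched a gene in the RefSeq gene table by Entrez identifier, with 0 symbols changed. The 62 control probe sets were left out. Probe sets were kept if their mean level over both arrays was at or above the median of all probe sets (an intensity of 62.6), and the kept probe set with the highest mean represented each gene, which left 11792 genes. Some items, among them 1 gene list, are not reported here.

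A gene was counted as higher or lower if its ratio reached 2-fold. Gene lists were fixed before the data were examined, and 37 of 40 had at least 3 members compared. For each of these the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these 2 arrays, not the conditions, and genes of a list are not independent of each other. As a gauge of measurement noise, the SD of a probe set's log2 ratio was taken from 3142 genes with exactly 2 kept probe sets, and was 0.336. It covers disagreement between probe sets and leaves out differences between cultures.

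Genes were named by a rule fixed at the same time as the lists. It took the 12 highest and 12 lowest genes whose kept probe sets all had the same sign, leaving out symbols of uncharacterised genes and antisense RNAs. It also took the 6 lowest and 4 highest reported miR-31 targets, with RDX, DICER1, ITGA5 and MIR31HG in any case, and up to 4 members of each other list with the largest absolute ratio. Other genes named were chosen after their values were seen, and the text says so.

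The calculation was tested on simulated data made from the control array with noise of SD 0.35 on the log2 scale and 200 changed genes (11873 genes compared). Of genes given a log2 change of 1.5 either way 86% were recovered at 2-fold, and of those given a change of 3, 92%. Of the unchanged genes 0.21% reached 2-fold. A list of 40 genes shifted by -0.3 had percentile 0.1, and 2 of 50 unshifted lists lay outside the central 95 percent. The simulated noise was the same at every level and independent between probe sets. In the real arrays the robust SD of ratios was 0.56 in the dimmest 2948 genes and 0.29 in the brightest 2948. The 0.21% therefore does not apply to dim genes. The unshifted lists held genes drawn at random, unlike lists of genes that vary together.

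Alternatives fixed in advance were quantile normalization, median centring, removal of a level-dependent trend (loess, span 0.3), pseudocounts of 1 and 64, no level filter, a stricter level filter that left 7723 genes, the mean of a gene's probe sets, leaving out probe sets named _s_at or _x_at, a threshold of 1.5-fold, and the reported targets without RDX. A search of 3' untranslated regions for miR-31 seed sites was planned and was not run, because sequences were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.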

Results

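The series asked which genes differ in U251 glioma cells when miR-31 is over-expressed. It holds 1 array of control-transfected cells and 1 array of miR-31-transfected cells, so all differences are between 2 RNA samples, without replicates. Across probe sets the log2 values of the arrays had a Pearson correlation of 0.968, which is a correlation across probe sets and not across samples.

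Genes of the antiviral interferon response were the gene list furthest above the control in the miR-31 array, with a median log2 ratio of 2.42 over 33 genes. Feedback inhibitors and output genes of the ERK pathway, which relays growth factor signals, were lower, with a median of -0.87 over 18 genes. Of 11792 genes compared, 441 were at least 2-fold higher in the miR-31 array and 186 at least 2-fold lower, while 94.7% lay within 2-fold. The dimmest 2948 genes held 215 of the higher and 71 of the lower genes, and the brightest 2948 held 37 and 35. For 145 genes with exactly 2 kept probe sets, the brighter one reached 2-fold. The other had the same sign in 131 of these and also reached 2-fold the same way in 55. At 4-fold, 60 genes were higher and 16 lower. The median log2 ratio over all genes was 0.03. Of the genes past 2-fold, 70.3% were higher, and this split depended on scaling: it was 57.5% after quantile normalization, 59.1% after removal of a level trend, 53.6% after median centring (a shift of -0.11 for every gene), 42.0% when ratios were centred on the bacterial hybridisation controls and 8.8% when centred on the poly-A spike-in controls. Those control classes were themselves higher in the miR-31 array, with medians of 0.19 over 18 probe sets and 0.55 over 24, and centring on them shifts every gene by -0.19 and -0.55. Ratios are therefore given relative to the deposited scale, and a shift common to all genes leaves the percentiles of lists as they are.

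Mature miR-31 was not measured by the probe sets analysed, so its over-expression was not checked here. MIR31HG, the host transcript of miR-31, had an intensity of 245 in the control and 495 in the miR-31 array (0.97). All 5 compared genes of the list around the MIR31 locus had ratios above 0, with a median of 0.34 at percentile 92.56, which lies below 0 when ratios are centred on the poly-A controls. With the mean of probe sets the median was 0.49 at percentile 98.04. FOCAD had 0.49, KLHL9 0.34 and MLLT3 0.22.

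**Figure D1:**
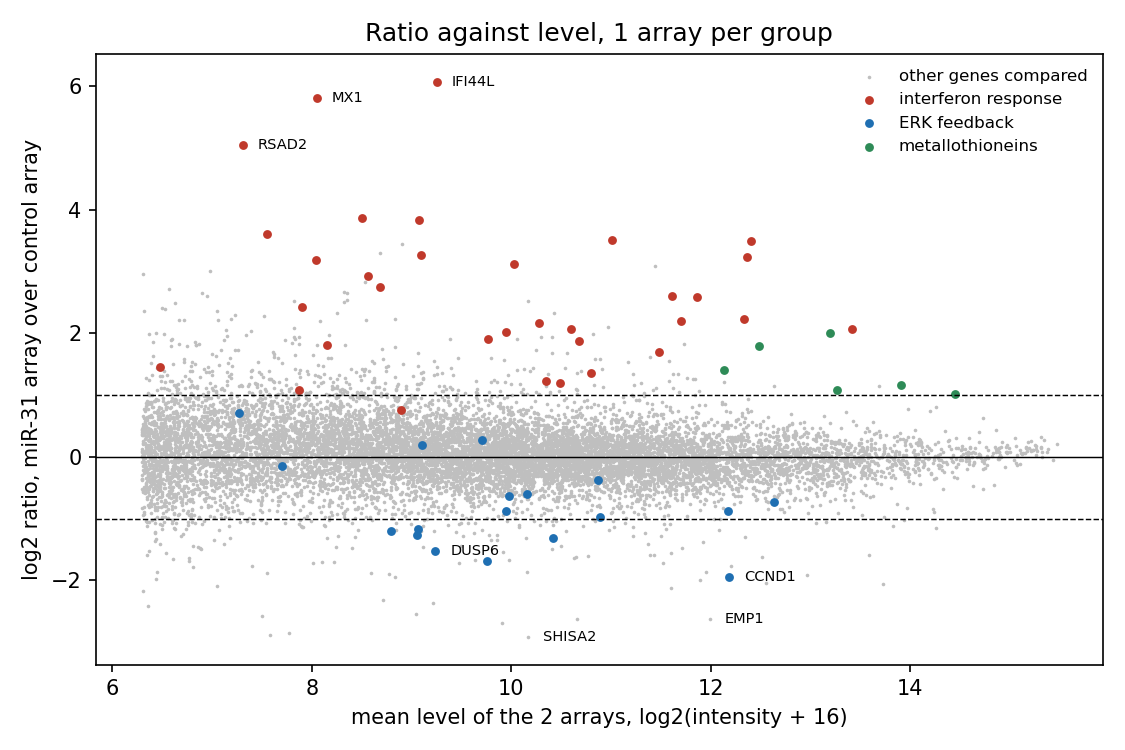
Log2 ratio of the miR-31 array over the control array (vertical axis) against the mean level of both arrays as log2(intensity + 16) (horizontal axis), 1 point per gene, with dashed lines at 2-fold. Interferon response genes lie above 0, reaching 6.07 for IFI44L, and 15 of 18 ERK feedback genes lie below 0.

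All 33 interferon-stimulated genes of the list that passed the level filter were higher in the miR-31 array, 32 of them by at least 2-fold, and the list median was 2.42 on the log2 scale. None of the 10000 level-matched random lists had a median that high. Of the members below the filter, IRF7, an interferon-regulated transcription factor, had 42.7 in the control and 16.7 in the miR-31 array, and EPSTI1 had 8.59 and 14.2; both were looked up after the other values were seen. IFI44L had an intensity of 58.3 in the control and 4983 in the miR-31 array, a log2 ratio of 6.07. MX1, an antiviral GTPase, had 19.4 and 1977 (5.82), and RSAD2, the antiviral protein viperin, 11.6 and 892 (5.04, with its other probe set at 4.77). OAS1, which makes the activator of RNase L, had 78.5 and 1370 (3.87). In the control, IFI44L, MX1, RSAD2 and OAS2 were below an intensity of 62.6, the minimum set for the mean of both arrays, so the size of their ratios depends on the pseudocount. Of the 12 highest genes 10 were on this list, the others being OAS2, CMPK2 (3.83), IFITM1 (3.51), ISG15 (3.49), IFIH1 and IFIT1 (3.23). The 3 probe sets of OAS2 had between 1.03 and 3.61, and IFIH1, a sensor of double-stranded RNA, had 3.26 on one probe set and 1.27 on another. Outside the list, DHRS3, a retinal reductase, had a log2 ratio of 3.44. DNAJC15 had 3.30 on one probe set and 0.06 on another.

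The 12 lowest genes came from several functions. SHISA2 had the lowest ratio, with 3136 in the control and 402 in the miR-31 array (-2.91). EMP1, an epithelial membrane protein, had 10117 and 1622 (-2.63, with 4 probe sets between -2.63 and -1.26). IER3, an early response gene, had -2.63, and SPHK1, which makes sphingosine 1-phosphate, had -2.37. ID4, an inhibitor of helix-loop-helix transcription factors, had -2.12, with 4 probe sets between -2.44 and -1.92. The others were CYB5R2 (-2.89), SHC4 (-2.85), TNFRSF19 (-2.70), ARHGAP36 (-2.58), GABBR2 (-2.54), UBE2NL (-2.31) and CCDC71 (-2.17). Another probe set of TNFRSF19 had -0.90, and the 4 of GABBR2 lay between -2.54 and -0.78. In the miR-31 array CYB5R2, ARHGAP36 and CCDC71 were below an intensity of 62.6.

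Genes reported as direct targets of miR-31 were slightly lower as a group, and most single members lay within 2-fold. Of 40 compared, 26 were lower and 14 higher, 4 were at least 2-fold lower and 0 at least 2-fold higher. The list median was -0.19, at percentile 0.2 of level-matched random lists. KHDRBS3, an RNA-binding protein, had the lowest ratio (-1.38, and -1.23 on its other probe set). SPRY4, an inhibitor of receptor tyrosine kinase signalling, had -1.17. STK40 had -1.08 and MMP16, a membrane-bound matrix protease, had -1.07, but another probe set of each had the opposite sign (0.50 and 0.11). MCM2, a subunit of the replicative helicase, and ETS1, a transcription factor, each had -0.69. At the other end SOX4 had 0.85, ITGA5 0.83, NUMB 0.78 and CREG1 0.75. RDX, which encodes the membrane-cytoskeleton linker radixin, was higher on all 4 kept probe sets, between 0.42 and 1.17. The value of 0.42, from its brightest probe set, lies below 0 when ratios are centred on the poly-A controls. DICER1, the enzyme that cuts microRNA precursors, had -0.17. Without the _s_at and _x_at probe sets the list lay at percentile 6.33, with a median of -0.10.

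**Figure D2:**
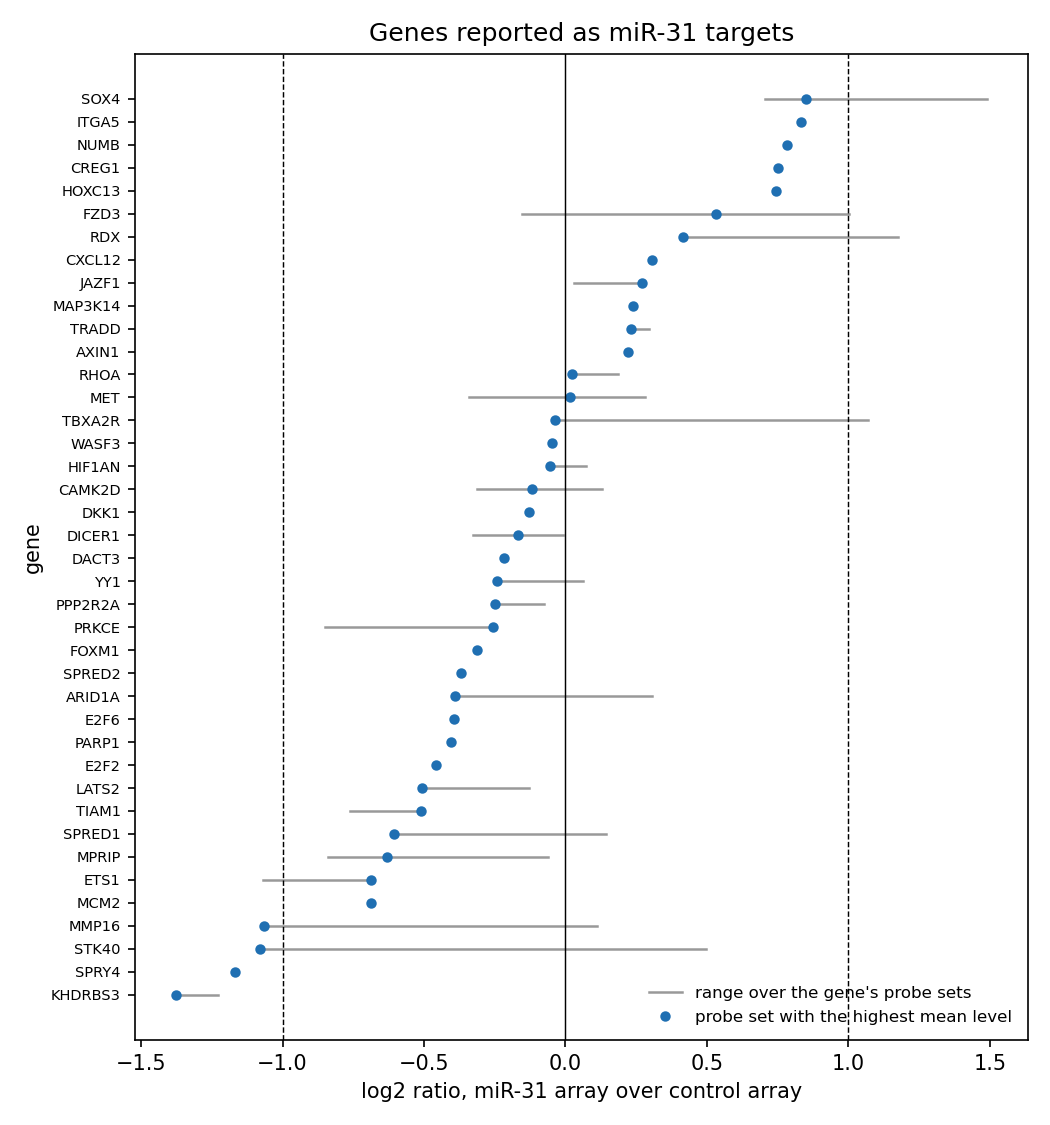
Log2 ratio of the miR-31 array over the control array for the 40 reported miR-31 targets compared, 1 row per gene. Points are the probe set with the highest mean level, lines the range over the gene's kept probe sets and dashed lines 2-fold; KHDRBS3 is lowest at -1.38 and SOX4 highest at 0.85.

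Feedback inhibitors and output genes of the ERK pathway were lower. Of 18 compared, 15 were lower and 7 at least 2-fold, and the median was -0.87, with 0 of 10000 random lists lower. CCND1, the G1 cyclin D1, had 9089 in the control and 2352 in the miR-31 array (-1.94), and FOSL1, an AP-1 subunit, had -1.69. DUSP6, a phosphatase of ERK, had -1.53 on its brightest probe set and -2.14 on another. DUSP7 had -1.31 on one probe set and 0.81 on another. Taking the mean of each gene's probe sets moved the list median to -0.60. Genes of the NF-kB list, which mixes NF-kB pathway genes and cytokine genes, lay on both sides of 0. Of 18 compared, 6 were at least 2-fold lower and 1 higher, with a median of -0.10 at percentile 9.56. Over the alternatives the median ran from -0.54, with no random list lower, over the 10 members left by a stricter level filter, to -0.03 without a level filter (percentile 29.15) and with the mean of probe sets (22.13). CXCL8, a neutrophil chemokine, had -2.06, IL11 -1.86 and LIF -1.72, while CXCL10, an interferon-inducible chemokine, had 1.80 from a control intensity of 41.6. All 6 lower genes are cytokine genes, the others being CXCL2 (-1.66), CXCL3 (-1.10) and IL6 (-1.07). The remaining cytokine genes compared were IL1B (-0.42) and CCL2 (0.35). The genes beyond the first 4 named were chosen after their values were seen. Immediate early genes had a median of -0.15 at percentile 5.26. It was -0.39 both with the stricter filter (percentile 0.01) and without _s_at and _x_at probe sets (0.13), and -0.01 without a level filter (41.2).

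TGF-beta and Hippo-YAP target genes and extracellular matrix genes were lower. The TGF-beta list had a median of -0.41, with 5 of 19 at least 2-fold lower, among them PMEPA1 (-1.76), the receptor TGFBR1 (-1.58) and ID3 (-1.15). The Hippo-YAP list had a median of -0.62, with 3 of 16 past 2-fold: ANKRD1 (-1.91), AMOTL1 (-1.11, with 4 probe sets between -1.39 and -0.44) and FJX1 (-1.04). In the matrix list the median was -0.29, with 4 of 32 at least 2-fold lower, including COL6A3 (-1.28) and THBS2 (-1.23), and 1 higher, COL11A1 (2.53), and the median was -0.19 with the mean of probe sets. No random list out of 10000 had a lower median than any of these 3 lists on the deposited scale. CCN2 (-0.89) is on all 3, and further members are shared between them, so the lists are not independent of each other. Matrix proteases had a median of -0.02 at percentile 36.3, with PLAT, tissue plasminogen activator, at -1.86 and the urokinase receptor PLAUR at -1.48 and -0.76 on another probe set.

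Cell cycle genes were lower by small amounts. All 32 G2/M genes were lower, with a median of -0.34, and none reached 2-fold. AURKB, a mitotic kinase, had -0.84, CENPA -0.79, PLK1 -0.77 and UBE2C -0.71. Of 29 S phase genes 25 were lower, with a median of -0.30, CDC45 at -0.71 and UNG at -0.67, while E2F1 had 0.70 on one probe set and -0.41 on another. Heat shock proteins had a median of -0.43 over 12 genes, with CRYAB at -1.72 as the only member past 2-fold. The random lists below these 3 medians numbered 0, 1 and 0 of 10000 for G2/M, S phase and heat shock.

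Metallothionein, sterol and respiratory chain genes were higher. All 6 metallothioneins compared, which bind zinc and copper, were at least 2-fold higher, with a median of 1.28, MT1E at 2.01 and MT1F at 1.80, although these genes are near-identical and a probe set may read several of them. Of 20 cholesterol synthesis genes 18 were higher and 3 past 2-fold, SREBF1 (1.30), SCD (1.28, with 4 probe sets between 0.12 and 1.28) and MSMO1 (1.06), with a median of 0.43, which lies below 0 when ratios are centred on the poly-A controls. Oxidative phosphorylation genes had a median of 0.15, with 25 of 29 higher and none past 2-fold, and this too lies below 0 when centred on the hybridisation or poly-A controls, and is 0.04 with median centring. The 5 histone genes compared had a median of 0.81 at percentile 99.41, with H2AC6 at 2.23 and H1-2 at 1.45, but a median of 0.23 without the level filter (percentile 80.96) and 1.45 with the stricter one.

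**Figure D3:**
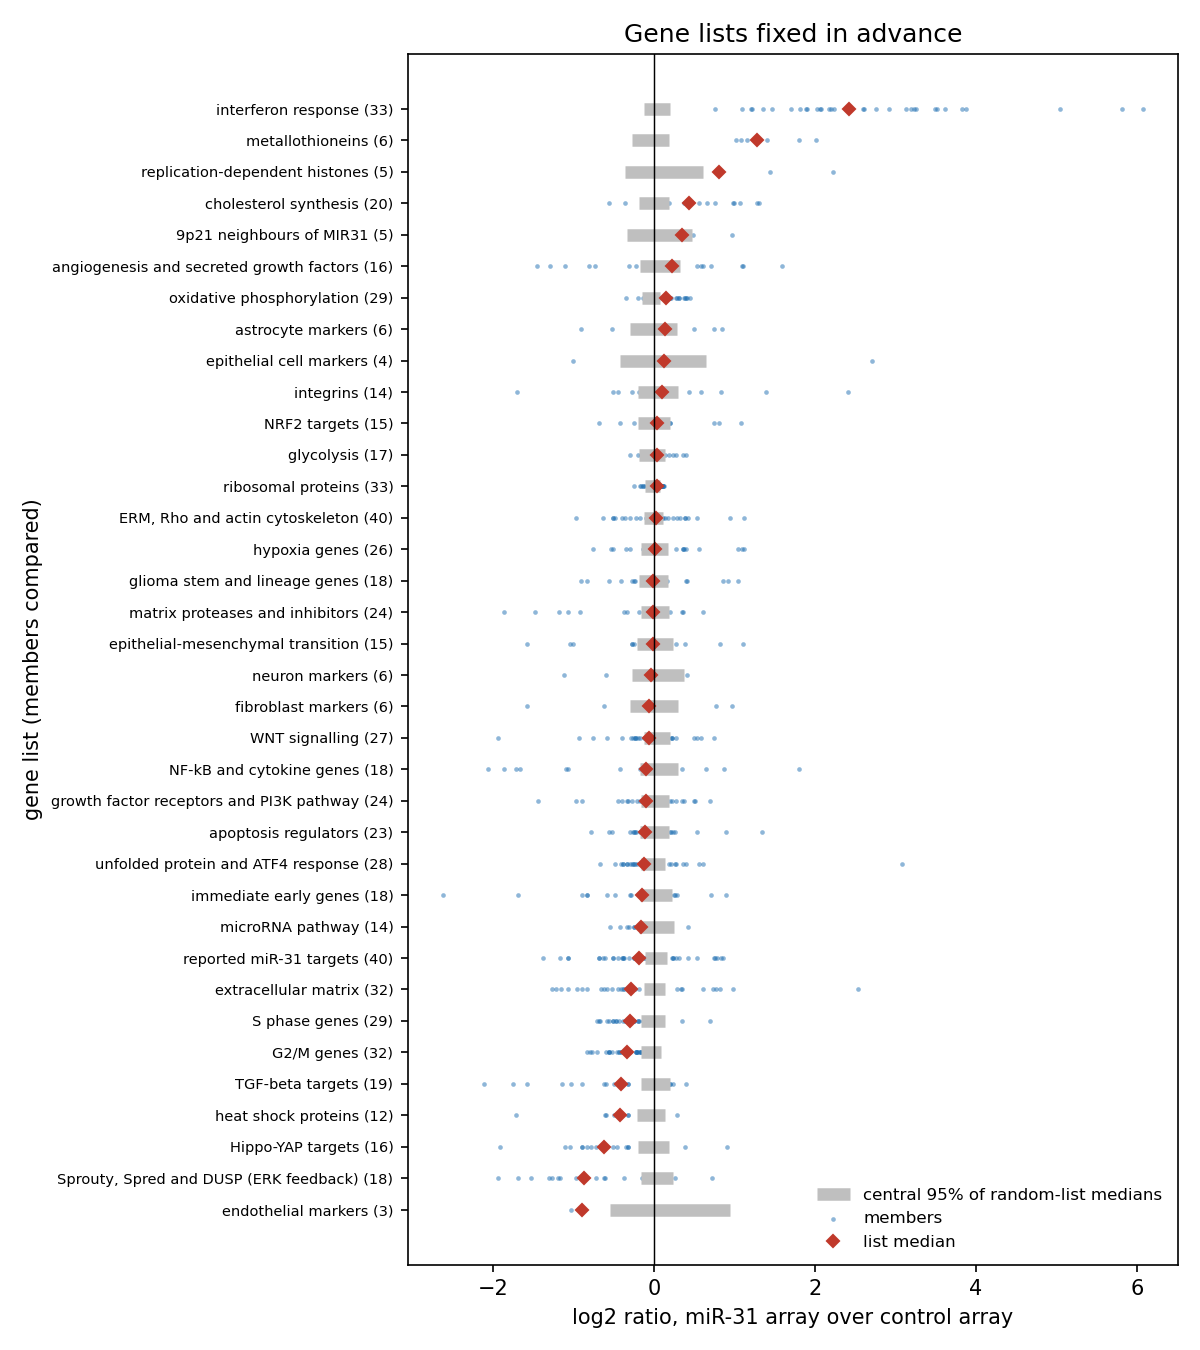
Log2 ratio of the miR-31 array over the control array for gene lists fixed in advance, 1 row per list with the number of members compared. Diamonds are list medians, points members and grey bars the central 95% of medians of level-matched random lists; the interferon list (2.42) lies furthest to the right.

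The hypoxia, cytoskeleton, integrin, protease, WNT, NRF2, glycolysis and ribosomal protein medians, all close to 0 and within the central 95% of random lists, had the opposite sign under at least 1 alternative. Hypoxia genes had a median of 0.01, although LOX (1.12), VEGFA (1.09) and BHLHE40 (1.04) were past 2-fold, each with another probe set near 0.60. The highest of the 4 probe sets of VEGFA had 1.58. Integrins had 0.10, and between -0.01 and 0.32 over the alternatives, with ITGA7 at 2.41 from a control intensity of 23.2, ITGB4 between 0.43 and 2.05 on 3 probe sets and ITGB3 between -1.70 and -0.05 on 6 probe sets. The cytoskeleton list, which includes RDX, had 0.02, with MYLK at 1.12 as the only member past 2-fold. Epithelial-mesenchymal transition genes had -0.02, and -0.13 with median centring, with S100A4 at -1.59, SNAI2 at -1.05 and KRT18 at -1.01. In the other direction OCLN had 1.11, with 3 probe sets between 0.11 and 1.11. WNT genes had -0.06, NRF2 targets 0.04, glycolysis 0.03, ribosomal proteins 0.03 and apoptosis regulators -0.12, with BCL2L11 at 1.34 on one probe set and below 0 on another. Over the alternatives the apoptosis median lay between -0.23 and -0.04. The microRNA pathway had -0.17 at percentile 3.8, with -0.25 at percentile 1.91 after quantile normalization and -0.03 at percentile 25.13 with the mean of probe sets. The unfolded protein list had -0.13, and between -0.24 and -0.08 over the alternatives, with DDIT4, an inhibitor of mTOR signalling, at 3.08. Glioma lineage genes had -0.01, between -0.19 and 0.00 over the alternatives, and growth factor receptors -0.10, between -0.21 and -0.08. The direction of secreted growth factors depended on the setting: the median was 0.22, but -0.23 with the stricter filter, -0.03 without a filter and 0.38 (percentile 98.89) with the mean of probe sets. TGFA had 1.59 and HBEGF -1.46.

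The cell type marker lists had at most 6 members each above the level filter, and most of their medians depended on the setting. Astrocyte markers had a median of 0.14, but -0.22 with the stricter filter and 0.40 (percentile 99.1) without a filter, with GFAP at 0.85 and GJA1 at -0.91. Fibroblast markers had -0.06, and -0.17 with median centring, but 0.97 (percentile 99.58) over the 3 left without _s_at and _x_at probe sets. Over the alternatives neuron markers, at -0.04, ran from -0.15 to 0.15, and epithelial markers, at 0.12, from -0.04 to 0.25. ELF3, an epithelial transcription factor, had 2.71 from a control intensity of 20.9. Endothelial markers had -0.90 at percentile 0.23, from 3 genes, and -0.59 without a level filter. Only 2 oligodendrocyte, 2 microglia and macrophage and 1 lymphoid marker passed the level filter, none of them at 2-fold. The 3' to 5' ratio of the GAPDH control was 0.95 in the control and 1.01 in the miR-31 array, and that of ACTB was 2.39 and 2.17.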

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

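The tests of the interferon pattern below were chosen after its values were seen.

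Among probe sets that the gene comparisons did not use, because the supplied annotation pairs them with several genes or none, 191 of 4824 that passed the level filter were at least 2-fold higher in the miR-31 array. A further 60 were at least 2-fold lower. These shares, 3.96% and 1.24%, are close to those of named probe sets that passed the filter, 3.58% and 1.67%, so the count does not set these probe sets apart. Their ratios ran from -2.79 to 3.37, and they were not assigned to genes.

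The interferon genes are the strongest pattern in these arrays. A difference in scale or a level-dependent trend is argued against, since the list median was 2.33 after quantile normalization and 2.29 after loess. Centring on a constant lowers the median by that constant alone and is no separate test. The largest such shift, -0.55 on the poly-A controls, left a median of 1.87. RNA or secreted interferon from immune cells stays open: of 24 microglia, macrophage and lymphoid markers 22 were named on the array, and 0 both passed the level filter and were at least 2-fold higher, but only 3 passed it. At any level 3 of the 22 were at least 2-fold higher and 0 lower, but dim values cannot be separated from background. The median intensity of the markers was 18.3 in the control and 27.3 in the miR-31 array, where the highest was 179. The interferon genes had median intensities of 432.3 and 2018.9. With 1 array per group, a difference between the 2 cultures other than miR-31, such as a response to the transfected nucleic acid, cannot be told apart from an effect of miR-31.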

How the results depend on the processing

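No paired analysis was possible because each group has 1 array, and no array could be left out. The analysis of miR-31 seed-matched genes and its alternatives were not run, since no 3' untranslated sequences were used here. Centring on spike-in controls, leaving out the interferon list and leaving out shared targets were chosen after seeing the data, the last with its bound set before its own result was seen. The number of genes at least 2-fold higher, 441, became 283 with a pseudocount of 64, 1184 without the level filter, 152 with a stricter level filter, 1376 at 1.5-fold, 266 centred on hybridisation controls and 124 centred on poly-A controls. The number of genes at least 2-fold lower, 186, became 280 with median centring, 1002 without the filter, 100 with the stricter filter, 793 at 1.5-fold, and 367 and 1279 with the same spike-in centrings. The filter and threshold alternatives change by construction how many genes can pass. Centring moves every ratio alike, and a larger pseudocount makes the ratio of every probe set smaller in size. The causes of the other changes given here were not tested. The interferon median of 2.42 became 2.33 with quantile normalization, 2.31 with median centring, 2.29 with loess, 2.60 and 2.21 with pseudocounts of 1 and 64, 2.24 without the filter, 2.18 with the stricter filter, 2.27 with the mean of probe sets and 2.24 without _s_at and _x_at probe sets. The ERK feedback median of -0.87 became -0.98 with median centring and -0.60 with the mean of probe sets. The reported targets' median of -0.19 became -0.30 with median centring, -0.12 with the mean of probe sets, -0.10 without _s_at and _x_at probe sets and -0.12 without shared members. Between 14 and 17 lists lay outside the central 95 percent under the alternatives, against 15. Calls that differed included those of the reported targets and histones (lost in at least 1 alternative) and of the MIR31 locus, NF-kB, immediate early, microRNA pathway, secreted growth factor, astrocyte and fibroblast lists (gained). Of 1387 values of 166 genes under the alternatives, 1327 moved by no more than the probe set SD, and 59 moved by more. Pseudocounts of 1 and 64 gave 5 and 17 of the 59, the mean of probe sets 25, and leaving out _s_at and _x_at probe sets 12. The level filters keep a gene's brightest probe set, and median centring shifts every gene by -0.11. Those settings could not move a value that far, so the 1327 overstates the stability. Among genes past 2-fold 1 changed sign, FGF5, from -1.11 to 0.23 without _s_at and _x_at probe sets. Of genes short of 2-fold 7 changed sign in 12 values, among them CNP, PECAM1 and HSPB8. Dim genes limit precision, since the robust SD of ratios was 0.56 in the dimmest 2948 genes and 0.29 in the brightest 2948.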

Other observations

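For the reported targets, removal of the level trend was planned; leaving out shared members was chosen after seeing the data, with its bound set before its own result. The other tests, and the lists and genes here that no rule named, were also chosen after seeing the data.

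Antigen presentation genes of MHC class I were higher: 15 of 16 compared, with a median log2 ratio of 0.63. NLRC5, their transcriptional activator, had 1.91, the immunoproteasome subunit PSMB9 1.61 and the peptide transporter TAP1 1.39, while B2M had 0.25 from an intensity of 34693. The class I HLA genes compared, which are near-identical in part, had ratios between 0.33 and 0.71. Of 12 interferon ligand genes listed, 11 were named on the array and 0 passed the level filter. Of 9 MHC class II genes 2 passed it. TXNIP, an inhibitor of thioredoxin, had 2.10, and CD24, a surface glycoprotein, 2.33.

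A list of ERK outputs and EGFR ligands drawn up from these arrays had a median of -1.64 over 17 genes, which is not independent evidence of its direction. It includes MAFF (-1.64, and -0.60 on another probe set), TRIB1 (-1.66) and DUSP4 (-1.27), while EGFR itself had 0.05, with 6 probe sets between -0.74 and 0.24, and TGFA 1.59.

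The lower level of ERK feedback genes is a second pattern. Scale and level trends are argued against, since the list median was -0.88 after quantile normalization and -0.86 after loess, with no lower random list; centring on a constant makes it lower by construction and tests nothing. A general loss of short-lived transcripts stays open. The 16 immediate early genes not on the ERK list had a median of -0.15, with a bootstrap SE of 0.25 from redrawing those genes. That SE treats the genes as independent and holds no spread between cultures. Even so, it was too wide to separate the median from -0.44, the ERK median divided by 2. Whether these genes also follow ERK output was not tested, so the comparison could not decide. The whole immediate early list ran from percentile 0.01 to 41.2 over the alternatives. An effect of miR-31 is untested beyond the 1 array.

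The lower median of reported miR-31 targets is a further pattern. A level-dependent trend is argued against by the list median, which was -0.19 both before and after the trend was removed. The percentile of 0.29 after removal adds nothing, because the random lists were matched on level. Whether members shared with the cell cycle and ERK feedback lists account for part of it cannot be told. Without SPRED1, SPRED2, SPRY4, MCM2 and FOXM1 the median went from -0.19 to -0.12 and the percentile from 0.2 to 3.67. The latter is past the bound of 2.5 set for this test. All 5 genes had ratios below the list median, so leaving them out raises it whatever the cause. Since 15 of 37 fixed lists lay outside the central 95% of random lists, a percentile outside that range is common here. Direct action of miR-31 on these genes was not tested.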
